A study of Homo sapiens with 8 samples.

How the data were processed

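Total RNA from 8 samples of MDA-MB-231, a triple-negative human breast cancer cell line with a mesenchymal character, was measured on Affymetrix Human Gene 2.1 ST arrays, 1 array per sample, per the labels. Samples were grouped by their titles into 3 untreated controls, 3 samples at a low dose and 2 samples at a high dose of a wild yam root extract, at 15 and 30 µg/mL for 24 h per the labels' treatment protocol. The source name and treatment fields of the same samples describe the groups differently: they give Boswellia serrata extract at 128 µg/mL for the low group and 3-O-acetyl-β-boswellic acid at 46 µg/mL for the high group. Both descriptions split the 8 samples in the same way, so each comparison of groups stands, but what the treated cells received remains unsettled. "Low dose" and "high dose" are used below as names of the groups. The labels do not say that each replicate was a culture of its own, so p-values of single genes measure only the spread between these samples, part of which may be technical. P-values of gene lists also rest on the correlation assumed between genes. Those of Fisher's exact test take genes as independent units and do not measure the spread between samples.

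The deposited table holds log2 expression values for 53617 probe sets on 8 arrays. Per the submitters' processing notes the Transcriptome Analysis Console was used. Its version, the summarization and the normalization are not given in the sources used here. The log base was inferred from the values: the highest deposited value, 12.10, lies above the natural logarithm of the ceiling of a 16-bit scanner (11.09) and far above its log10 (4.816), and the lowest is -0.00. The values were used as deposited. The 75th percentile of the tested genes differed between arrays, from 4.54 to 4.94, so the arrays had not been forced to a common distribution at the level of these genes. The table holds no measure of background, so a dim gene could not be told from an absent one, and the number of arrays limits the precision.

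Probe sets were named through the platform annotation supplied for this table. Of the 53617 rows, 23558 carried 1 gene symbol, 2155 carried several and 27904 were unnamed here. Of the rows with 1 symbol, 22271 matched a current gene record by Entrez identifier and 3 symbols were updated. Only rows with 1 symbol were tested by gene. For the 618 genes with several such rows, the row with the highest mean over all arrays was kept, which left 22109 genes. Several well-known genes had no row with a single symbol and were not analysed here.

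A linear model with 1 mean per group was fitted over all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes), so that the groups shared 1 estimate of the spread with 5 residual and 6.0 prior degrees of freedom. The 3 comparisons were high dose against control, low dose against control and high dose against low dose. P-values were adjusted over the 22109 genes of each comparison by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05, and fold changes are given on the log2 scale with their standard errors (SE). Of 568 planned entries in 29 gene lists, 475 were measured. The lists cover stress, signalling, cell cycle and metabolic programmes together with markers of 3 cell types that the samples should not hold. They were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 29 lists. Camera with an estimated correlation, camera on ranks and fry, which asks whether the genes of a list move one way on balance, were run as alternatives. The count "adjusted over the list alone" uses Benjamini-Hochberg over the members of that list.

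Genes were named by a rule set before the data were examined, as were the lists, the design and the alternative settings. For each treated group against control it took the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap between the groups, leaving out small RNAs, pseudogenes, antisense and uncharacterized genes. It added up to 4 called members of each called list, and up to 3 called long non-coding RNAs per direction. For high against low it took 5 genes per direction, by the smallest p where fewer passed. Genes named in text outside this rule are said to be so.

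The 2 treated groups compared with the same 3 controls share the chance values of those controls. Unchanged groups were therefore simulated 100 times against shared controls, with each gene's own residual spread, equal in all groups, and no deviations shared between arrays. The scripts were tested on simulated data with 200 changed genes among 22109 before use. For low dose against control, 60% of genes changed 2-fold and 96% of genes changed 4-fold were recovered, and 3.70% of the calls were false. For high dose against control these shares were 47%, 90% and 6.16%. These data were drawn once, with independent arrays and equal spread in all groups. The real arrays differ in both respects, so the shares are not error rates of the real calls.

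The titles number the replicates. Deviations from the group means were compared between same-numbered arrays before the fits with and without a replicate block were compared. For control and low arrays the correlations of the 3 pairs were 0.103, 0.153 and 0.203 across genes, all over 0.1, so the numbers were taken to pair these 6 arrays, a pairing that comes from the data and not from a statement in the labels. Control 1 correlated slightly more with low 2 (0.122) than with low 1, and control 2 with low 1 at 0.065. Deviations cancel within a group, so a shared deviation of control 3 and low 3 also raises the values among the other arrays. The correlations are therefore not separate evidence for pairing by number, and show mainly that control 3 and low 3 deviated together. The high arrays did not pair by number, with correlations of 0.094 and -0.049 with control and 0.214 and -0.177 with low. The alternative settings set beforehand changed the rows tested, the row kept per gene, a filter on dim genes, the normalization (quantile, or array medians subtracted), the prior variance, array weights, the arrays in the fit, the replicate block, the threshold and the list test, and left out each array in turn. Fits without control 3 and low 3, without control 3, low 3 and high 2, and with the block over control and low arrays alone were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.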

Results

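The deposited arrays measured the transcriptome of MDA-MB-231 cells, a triple-negative breast cancer line, after 24 h. Cells were untreated (3 samples) or had a low dose (3 samples) or a high dose (2 samples) of a plant preparation described as sublethal. The titles and treatment protocol name it as wild yam (Dioscorea villosa) root extract at 15 and 30 µg/mL, whereas the source names give Boswellia serrata extract at 128 µg/mL and 3-O-acetyl-β-boswellic acid at 46 µg/mL for the same groups of samples. The study asked how sublethal treatment changed messenger and long non-coding RNAs. Arrays of 1 group correlated at 0.972 to 0.994 across genes. Control 3, low 3 and high 2 stood apart from the other arrays, with 75th percentiles of the log2 value over genes of 4.73, 4.54 and 4.54 against 4.80 to 4.94 elsewhere. The leading 2 principal components held 31.6% and 30.1% of the variance, the first of which set control 3 apart from the rest.

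At the low dose the largest rises were in inflammatory and immediate early genes. PTGS2, which encodes the inducible cyclooxygenase, rose by 3.26 ± 0.33 (SE; log2 scale; 3 against 3 arrays; adjusted p = 0.00104). CXCL8, the neutrophil chemokine interleukin 8, rose by 3.14 ± 0.15 (adjusted p = 5.08e-06), an 8.83-fold difference. All 28 genes of the G2/M and mitosis list fell, but the list was not called with an estimated correlation (adjusted p = 0.144) and control 3 stood above the other controls in it. Fry gave this list an adjusted p of 0.0107. Large falls among mitotic genes were those of NDC80 of the outer kinetochore (-2.01 ± 0.33, adjusted p = 0.00803) and CDK1, the kinase that drives entry into mitosis (-1.84 ± 0.29, adjusted p = 0.00668). In all, 264 genes were higher and 400 lower than in the controls, of which 164 and 214 changed at least 2-fold. At an unadjusted p under 0.05 there were 1190 higher and 1938 lower genes. With the replicate number as a block, since the numbers were taken to pair the control and low arrays, 483 genes were higher and 576 lower. With the block over these 6 arrays alone, a fit chosen after seeing the data, there were 291 and 310. Quantile normalization moved the split from 264 higher and 400 lower to 612 and 570. Leaving out 1 array other than control 3 gave fewer calls: 173 higher and 213 lower without control 1, 175 and 257 without control 2, 117 and 244 without low 1, 96 and 170 without low 2, and 252 and 188 without low 3. Without control 3 there were 250 higher and 408 lower.

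The other large rises at the low dose were KLF2 (2.98 ± 0.27), a transcription factor of the Krüppel-like family, the small GTPase gene RHOB (2.96 ± 0.15), and the MAP kinase phosphatase gene DUSP10 (2.67 ± 0.31). Next came the stress transcription factor ATF3 (2.66 ± 0.30), the immediate early transcription factor EGR1 (2.65 ± 0.35) and HMOX1 (2.60 ± 0.27), which encodes the heme-degrading enzyme heme oxygenase 1. They were followed by INSIG1 (2.54 ± 0.17), a sterol-regulated brake on SREBP processing, and the cytokine gene IL1A (2.46 ± 0.31). The other large falls were PBK (-1.94 ± 0.29), the centrosomal kinase gene NEK2 (-1.86 ± 0.35), the cohesion establishment factor DSCC1 (-1.85 ± 0.20) and FAM83D (-1.84 ± 0.20). After these came the Aurora A activator BORA (-1.82 ± 0.27), the spindle protein gene DLGAP5 (-1.82 ± 0.30), NUF2 (-1.76 ± 0.34), which lies with NDC80 in one complex, and SGO1 (-1.76 ± 0.23), which protects centromeric cohesion. Their adjusted p-values lay between 7.21e-06 and 0.0185. The calls of NEK2 and NUF2 ended under 4 and 5 of 22 alternative settings, with changes between -2.12 and -1.14 and between -2.08 and -1.24.

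All 28 measured genes of the G2/M and mitosis list fell at the low dose, and all 28 passed when adjusted over the list alone, with a median change of -1.49. Besides NEK2, CDK1 and DLGAP5 they included CCNA2, which encodes cyclin A2 (-1.70 ± 0.20). Camera gave an adjusted p of 3.34e-37 for this list, and the adjusted p = 0.144 with an estimated correlation. Control 3 lay above the other controls in this list, with a mean log2 level of 7.26 against 6.61 and 6.58, and without it the median change was -1.31 (adjusted p = 4.60e-38). In the list of DNA replication and G1/S genes 17 of 30 fell and none rose (27 fell when adjusted over the list alone; median -0.90). Examples were POLE2, a subunit of DNA polymerase epsilon (-1.58 ± 0.16), the replication initiation factor MCM10 (-1.40 ± 0.19), cyclin E2 (CCNE2, -1.29 ± 0.16) and the clamp loader subunit RFC3 (-1.25 ± 0.17). Its adjusted p was 1.39e-27, and adjusted p = 0.144 with an estimated correlation. Of 12 genes of homologous recombination 9 fell (10 adjusted over the list alone; median -1.26). They included RAD51AP1 (-1.57 ± 0.25), the helicase genes BRIP1 (-1.46 ± 0.20) and DNA2 (-1.30 ± 0.18) and the nuclease gene EXO1 (-1.35 ± 0.19). The list passed at 5.19e-14, with adjusted p = 0.140 with an estimated correlation. Of 8 replication-dependent histone genes H2AC14 fell (-0.96 ± 0.18; 2 fell adjusted over the list alone), and the list's adjusted p of 0.0282 became 0.192 with an estimated correlation and 0.0552 without control 1.

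**Figure D1:**
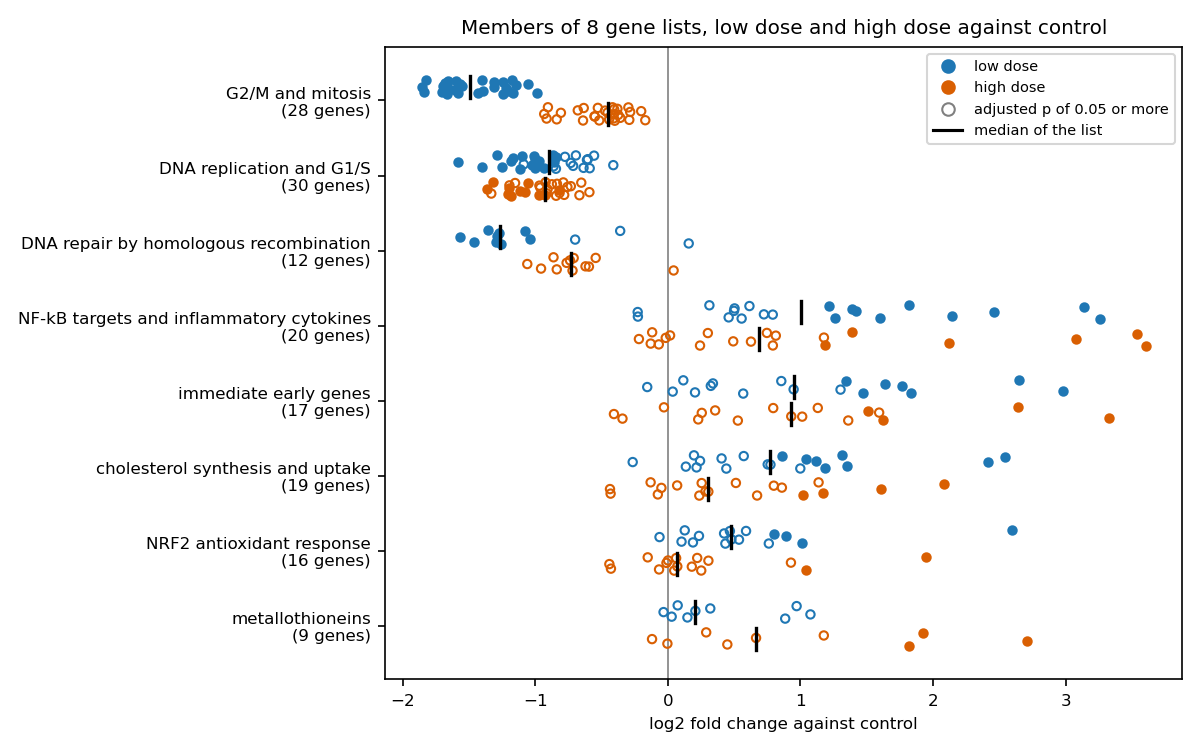
Log2 fold change against control (horizontal axis) of each measured member of 8 gene lists at the low dose (blue, 3 arrays against 3) and the high dose (orange, 2 arrays against 3). Filled points have an adjusted p under 0.05, open points do not, and black bars are medians: the mitotic list has a median of -1.49 at the low dose and -0.45 at the high dose, while the replication list has -0.90 and -0.93.

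NF-κB targets and inflammatory cytokines formed the list with the most rises at the low dose: 10 of 20 genes rose and none fell (15 adjusted over the list alone; median 1.00). They included PTGS2, CXCL8, IL1A and TNFAIP3, which encodes the feedback inhibitor A20 (2.14 ± 0.20). Camera gave an adjusted p of 1.99e-20, with adjusted p = 0.140 with an estimated correlation. Among 17 immediate early genes 7 rose (10 adjusted over the list alone; median 0.95, or 0.69 to 1.48 when 1 array was left out), such as KLF2, EGR1, the AP-1 gene JUNB (1.83 ± 0.28) and KLF6 (1.76 ± 0.24). The list passed at 2.92e-13, and adjusted p = 0.192 with an estimated correlation. Of 11 glucocorticoid receptor targets 3 rose, the transcription factor gene KLF9 (1.74 ± 0.21), the NF-κB inhibitor gene NFKBIA (1.42 ± 0.21), which is also on the NF-κB list, and the circadian gene PER1 (1.17 ± 0.21). This list had 7 rises adjusted over the list alone, a median of 0.46 and an adjusted p of 2.70e-07 (adjusted p = 0.144 with an estimated correlation).

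Of 19 genes of cholesterol synthesis and uptake 8 rose at the low dose and none fell (13 adjusted over the list alone; median 0.77). INSIG1 rose most, followed by HMGCS1 (2.42 ± 0.19), which makes the precursor of mevalonate, and by MSMO1 (1.35 ± 0.15) and LSS (1.32 ± 0.23), enzymes of the later steps. The adjusted p was 1.45e-18, with adjusted p = 0.147 with an estimated correlation. In the fatty acid synthesis list 1 of 11 genes rose, ACSS2 (1.20 ± 0.22), which makes acetyl-CoA from acetate (2 adjusted over the list alone; median 0.28; adjusted p = 0.00547, and adjusted p = 0.393 with an estimated correlation). Without control 3 the median of this list was 0.13, at an adjusted p of 0.0250. The list of cholesterol efflux genes driven by the LXR receptors was not called (adjusted p = 0.985).

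Parts of several stress and clearance lists rose at the low dose, while the lists of endoplasmic reticulum chaperones and cytosolic heat shock proteins were not called (adjusted p = 0.0803 and 0.613). Of 16 NRF2 antioxidant genes 4 rose (6 adjusted over the list alone; median 0.47). These were HMOX1, AKR1C1, which reduces carbonyls (1.01 ± 0.19), the glutathione synthesis gene GCLC (0.89 ± 0.18) and the cystine transporter gene SLC7A11 (0.80 ± 0.18). Camera gave an adjusted p of 3.63e-10 for the list and adjusted p = 0.179 with an estimated correlation. Of 19 autophagy and lysosome genes 6 rose (7 adjusted over the list alone; median 0.42). Among them were the autophagosome gene GABARAPL1 (1.40 ± 0.18), the cargo receptor SQSTM1 (1.37 ± 0.23), the lysosomal sialidase NEU1 (1.32 ± 0.22) and the protease gene CTSL (1.19 ± 0.20). The list stood at 3.20e-10 and adjusted p = 0.192 with an estimated correlation. The ATF4 and CHOP list had 5 rises among 21 genes (7 rises and 1 fall adjusted over the list alone; median 0.48; adjusted p = 4.16e-06, and adjusted p = 0.376 with an estimated correlation). The risen genes were ATF3, CEBPB (1.36 ± 0.22), the phosphatase subunit PPP1R15A (1.33 ± 0.28), DDIT3, which encodes CHOP (1.31 ± 0.16), and SLC7A11. Of 17 p53 targets 3 rose (5 adjusted over the list alone; median 0.13), at a list adjusted p of 0.000234 and adjusted p = 0.192 with an estimated correlation. They were the stress cytokine GDF15 (2.13 ± 0.20), the cyclin-dependent kinase inhibitor CDKN1A (2.00 ± 0.30) and TP53INP1 (1.53 ± 0.14). Control 3 carried a large part of the medians: without it they were 0.26 for NRF2, 0.17 for autophagy and lysosome and 0.27 for ATF4 and CHOP genes, all 3 lists still being called. The calls of SLC7A11, AKR1C1, PPP1R15A and GCLC ended under 9, 7, 7 and 6 of 22 alternative settings.

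Further lists were called at the low dose on few of their genes, and none of them was called with an estimated correlation, the lowest adjusted p over the 29 lists then being 0.140. In the hypoxia and glycolysis list NDRG1 rose (1.15 ± 0.17; 1 of 21 genes; list adjusted p = 4.16e-06). The xenobiotic list held rises of the cytochrome gene CYP1B1 (1.33 ± 0.26) and TIPARP (1.08 ± 0.19), both targets of the aryl hydrocarbon receptor (2 of 14; 0.000305). In the interferon list IRF9 rose (1.10 ± 0.21; 1 of 20; 0.0191), whose 2 rows differed in size, at 0.14 and 1.10. The mesenchymal list held a rise of the collagenase gene MMP1 (1.24 ± 0.15) and a fall of CCN2, a matricellular protein gene (-1.34 ± 0.28), among 24 genes, with an adjusted p of 0.00572 that became 0.165 without control 3. Metallothioneins (median 0.21; adjusted p = 0.00113) and apoptosis regulators (median 0.21; adjusted p = 0.0182, and 0.128 without control 3) held no gene that passed. Ribosomal protein genes had a median of -0.21 (adjusted p = 0.0111) with a fall of RPS25 (-0.76 ± 0.18; the call ended under 15 of 22 alternative settings). Nuclear genes of oxidative phosphorylation had a median of -0.24 (adjusted p = 0.00137). Without low 3 these lists had medians of -0.11 and -0.15 and adjusted p-values of 0.0624 and 0.0670. The calls of CCN2, IRF9 and CYP1B1 ended under 7, 6 and 5 of 22 alternative settings. The interferon list had 0.0669 without control 2. The medians of the hypoxia and xenobiotic lists, 0.32 and 0.19, were 0.08 and 0.04 without control 3, where both lists were still called.

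At the high dose 6 of 20 NF-κB and cytokine genes rose and 11 of 30 replication genes fell, in lists that were not called with an estimated correlation (adjusted p = 0.203 and 0.211). Fry gave an adjusted p of 0.0206 for both lists. CXCL8 rose by 3.61 ± 0.16 (SE; log2 scale; 2 against 3 arrays; adjusted p = 3.85e-06), and PTGS2 by 3.54 ± 0.37 (adjusted p = 0.00217). GDF15 rose by 3.51 ± 0.22 (adjusted p = 5.03e-05) and EGR1 by 3.32 ± 0.39 (adjusted p = 0.00466). The metal-binding protein gene MT1E rose by 2.71 ± 0.34 (adjusted p = 0.00615). Among the falls were FAM111B, a gene expressed with DNA replication (-1.59 ± 0.20, adjusted p = 0.00560), and SKP2, which encodes the ubiquitin ligase subunit that targets p27 (-1.44 ± 0.28, adjusted p = 0.0444). In all, 94 genes were higher and 86 lower, 86 and 63 of them at least 2-fold. These compare with 671 and 2526 at an unadjusted p under 0.05. The median change over all 22109 genes was -0.12. Quantile normalization gave 326 higher and 133 lower genes, and subtracting array medians 119 and 57, so that the share of higher genes among the calls went from 52.2% to 71.0% and 67.6%. It went the other way with the replicate block (197 higher and 1031 lower) and with array weights (235 and 769). The block joins high 2 to control 2 and low 2, although its deviations correlated at -0.049 and -0.177 with theirs and at 0.274 with low 3. Its counts at the high dose are therefore uncertain. The counts depended on single arrays: without control 3 they were 250 and 740, without control 1 41 and 7, and without control 2 42 and 11. They were without high 1 13 and 6, without high 2 23 and 1, without low 1 58 and 21, and without low 2 59 and 28. Of the 45 genes named for this comparison, 6 kept the call under every alternative setting that tested them (CXCL8, DDIT3, GDF15, INSIG1, MT1M and RHOB). MT1M was tested under 20 settings and the others of these under 21, since the filter on dim genes removed it. All 45 kept their direction.

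**Figure D2:**
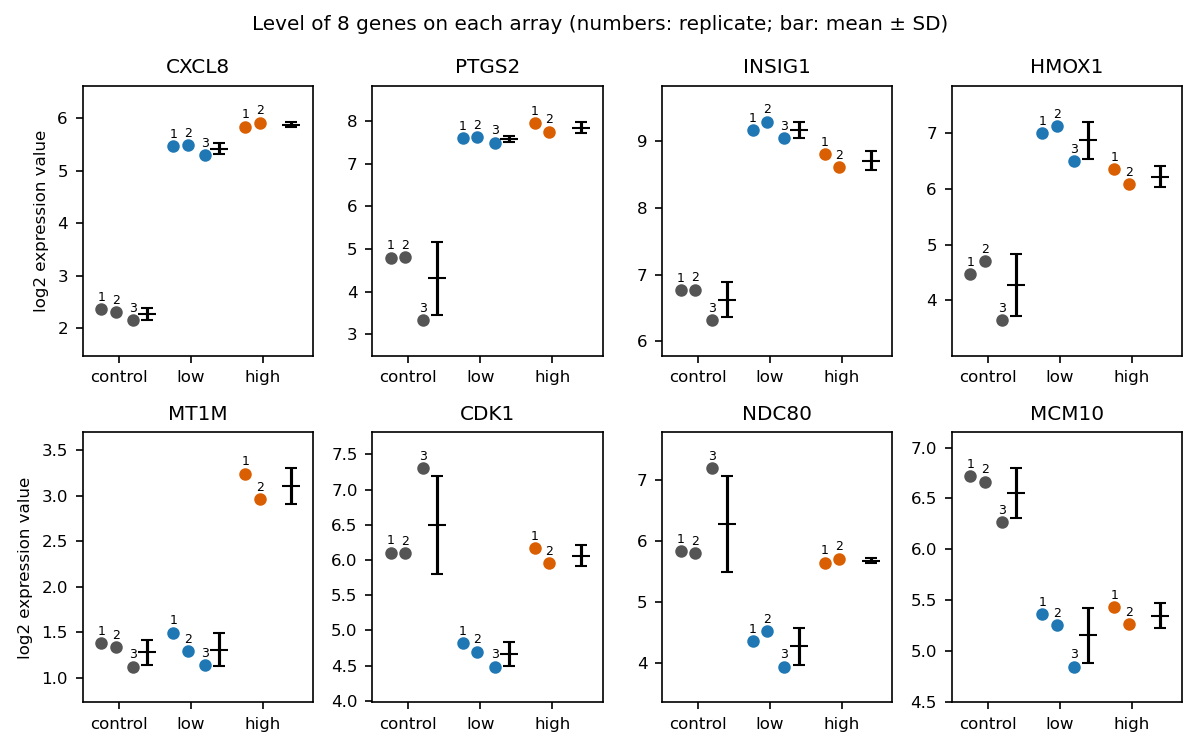
Log2 expression value (vertical axis, with its own range per gene) of 8 genes on every array, by group. Points are arrays with their replicate numbers, and bars show the group mean and SD. CXCL8 lies at 2.16 to 2.36 on the control arrays and at 5.29 to 5.92 on the treated arrays. CDK1 is lower on the low arrays, at 4.49 to 4.81, than on the high arrays, at 5.95 and 6.16, and control 3 stands above the other controls at 7.30.

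The other large rises at the high dose were IL1A (3.08 ± 0.34), RHOB (2.74 ± 0.17), KLF2 (2.64 ± 0.30), ATF3 (2.60 ± 0.34) and KYNU (2.27 ± 0.26), an enzyme of tryptophan breakdown. The other large falls were TRBJ2-6 (-1.68 ± 0.26), a T cell receptor gene segment (mean 3.41 in controls), the collagen gene COL8A1 (-1.50 ± 0.27), KBTBD6 (-1.50 ± 0.20) and ALDH1B1 (-1.45 ± 0.24), a mitochondrial aldehyde dehydrogenase gene. Close to these were CDCA7 (-1.44 ± 0.18), the polo-like kinase gene PLK2 (-1.43 ± 0.18), the ribosomal protein paralog RPL39L (-1.42 ± 0.28) and the LIM domain gene AJUBA (-1.42 ± 0.21). Their adjusted p-values lay between 5.03e-05 and 0.0490. RPL39L is a near-identical relative of another ribosomal protein gene, so its value is uncertain. Its call ended under 11 of 21 alternative settings, that of SKP2 under 10 and that of COL8A1 under 9.

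In the DNA replication and G1/S list 11 of 30 genes fell at the high dose and none rose, and all 30 passed when adjusted over the list alone (median -0.93). Examples are CDC6 (-1.37 ± 0.24), which loads the replicative helicase, its subunit MCM6 (-1.32 ± 0.20), MCM10 (-1.20 ± 0.21) and CCNE2 (-1.20 ± 0.18). The calls of these genes ended under 8, 7, 9 and 7 of 21 alternative settings. Camera gave an adjusted p of 6.96e-24, with adjusted p = 0.211 with an estimated correlation. No gene of homologous recombination passed over all genes, but 11 of 12 did so as lower when adjusted over the list alone (median -0.73; list adjusted p = 2.78e-07, and adjusted p = 0.211 with an estimated correlation). No gene of the 28 in the G2/M and mitosis list passed, and 4 did so adjusted over the list alone. Its median was -0.45, with an adjusted p of 1.04e-05, adjusted p = 0.533 with an estimated correlation, and 0.136 without control 3, where the median was -0.29. Without control 3, low 3 and high 2, which leaves 1 high array, the median was -0.12. The median of level-matched random lists of 28 genes lay between -0.48 and 0.08 in this comparison.

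Of the 20 NF-κB targets and cytokines 6 rose at the high dose (10 adjusted over the list alone; median 0.69; adjusted p = 2.83e-16, and adjusted p = 0.203 with an estimated correlation). They were led by CXCL8, PTGS2, IL1A and TNFAIP3 (2.12 ± 0.23). Of 17 immediate early genes 4 rose, EGR1, KLF2, JUN (1.62 ± 0.23) and KLF6 (1.51 ± 0.27). Adjusted over the list alone 8 did (median 0.93; adjusted p = 2.57e-13, and adjusted p = 0.260 with an estimated correlation). Control 3 lay below the other controls in this list, with a mean log2 level of 5.16 against 6.28 and 6.33, and without it the median was 0.41, with the list still called. Of 19 cholesterol genes 4 rose, INSIG1 (2.09 ± 0.19), HMGCS1 (1.61 ± 0.21), the isomerase gene IDI1 (1.17 ± 0.17) and MSMO1 (1.02 ± 0.16). Adjusted over the list alone 8 rose (median 0.31, or 0.17 to 0.53 when 1 array was left out; adjusted p = 1.19e-11, and adjusted p = 0.260 with an estimated correlation). Metallothioneins, small metal-binding proteins, had 3 rises among 9 genes, MT1E, MT1F (1.92 ± 0.26) and MT1M (1.82 ± 0.18), and 5 adjusted over the list alone (median 0.67; adjusted p = 6.75e-11). This was the 1 list of the 16 called at the high dose that was also called with an estimated correlation (adjusted p = 0.0350). MT1M lay in the controls near the 10th percentile of the tested genes and was not shown to be above background there, so its rise is a lower bound if it was not. The metallothionein genes are near-identical in sequence, so the value of each member is uncertain.

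Smaller parts of other lists rose at the high dose. HMOX1 rose by 1.95 ± 0.30 and SLC7A11 by 1.05 ± 0.21 among 16 NRF2 genes (3 adjusted over the list alone; median 0.07; adjusted p = 0.000486, and adjusted p = 0.446 with an estimated correlation). ATF3, DDIT3 (1.67 ± 0.17) and SLC7A11 rose among 21 ATF4 and CHOP genes (5 rises and 3 falls adjusted over the list alone; median 0.22; adjusted p = 0.000340, and adjusted p = 0.543 with an estimated correlation). Without control 3 both lists had an adjusted p of 0.0547, with medians of -0.01 for NRF2 and 0.02 for ATF4 and CHOP genes. GDF15 and TP53INP1 (1.24 ± 0.16) rose among 17 p53 targets (3 adjusted over the list alone; median 0.08; adjusted p = 0.000554, and adjusted p = 0.260 with an estimated correlation). GABARAPL1 (1.40 ± 0.21) and MAP1LC3B (0.84 ± 0.16), which encode autophagosome proteins, rose among 19 autophagy and lysosome genes (6 adjusted over the list alone; median 0.10; adjusted p = 1.81e-07, and adjusted p = 0.345 with an estimated correlation). NFKBIA (1.18 ± 0.24) was the 1 of 11 glucocorticoid receptor targets that rose (2 adjusted over the list alone; median 0.47; adjusted p = 6.40e-06, and adjusted p = 0.211 with an estimated correlation). Without control 3 the medians were 0.28 for these targets, 0.02 for p53 targets and 0.06 for autophagy and lysosome genes, with the 3 lists still called. ADM (0.90 ± 0.17), which encodes the vasodilator adrenomedullin, rose in the hypoxia list, whose median (-0.05) and mean (0.11) differed in sign. Its adjusted p of 0.00471 became 0.608 with an estimated correlation, 0.160 without control 3 and 0.182 without high 1. No gene passed in the interferon list (median 0.24; adjusted p = 6.91e-06, and adjusted p = 0.203 with an estimated correlation). The same held for ribosomal protein genes (median -0.32; 0.00214) and nuclear genes of oxidative phosphorylation (median -0.42; 0.000246), both at adjusted p = 0.508 with an estimated correlation. Quantile normalization left the ribosomal list at 0.0762. The calls of ADM and MAP1LC3B ended under 11 of 21 alternative settings, and those of NFKBIA and SLC7A11 under 10.

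The 2 doses changed genes in the same direction where both were called: 73 genes were higher at both doses, 53 lower at both, and 0 went opposite ways. Lists of these sizes drawn independently would share 1.12 and 1.56 genes. Both comparisons use the same controls, which raises shared calls and makes opposite calls rarer even for unrelated treatments. Shared calls were not counted in the simulation of unchanged groups, so these numbers do not measure agreement beyond the shared controls. Across the 22109 genes, which are not independent replicates, the log2 changes correlated at r = 0.621, and 69.5% had the same sign. Unchanged groups simulated against the same 3 controls gave a mean r of 0.449 (highest 0.474) and 64.8%. The simulated arrays were independent of each other, so the deviations that control, low and high arrays shared are not in these values. They also had equal spread in all groups, unlike the real arrays. The SD of the difference between 2 arrays was 0.253 to 0.477 among controls, 0.232 to 0.372 among low arrays and 0.363 between the high arrays. Noisier controls raise the correlation of unchanged groups, so the excess over 0.449 may be overstated. With the replicate block the observed r was 0.516, for which no matching simulation was made. The covariance was 0.0729 against 0.0249 simulated, a difference of 0.048. The 3 controls cannot be split with at least 2 in each part, so part of the excess may come from the shared controls, and part of the covariance from the shared deviations.

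**Figure D3:**
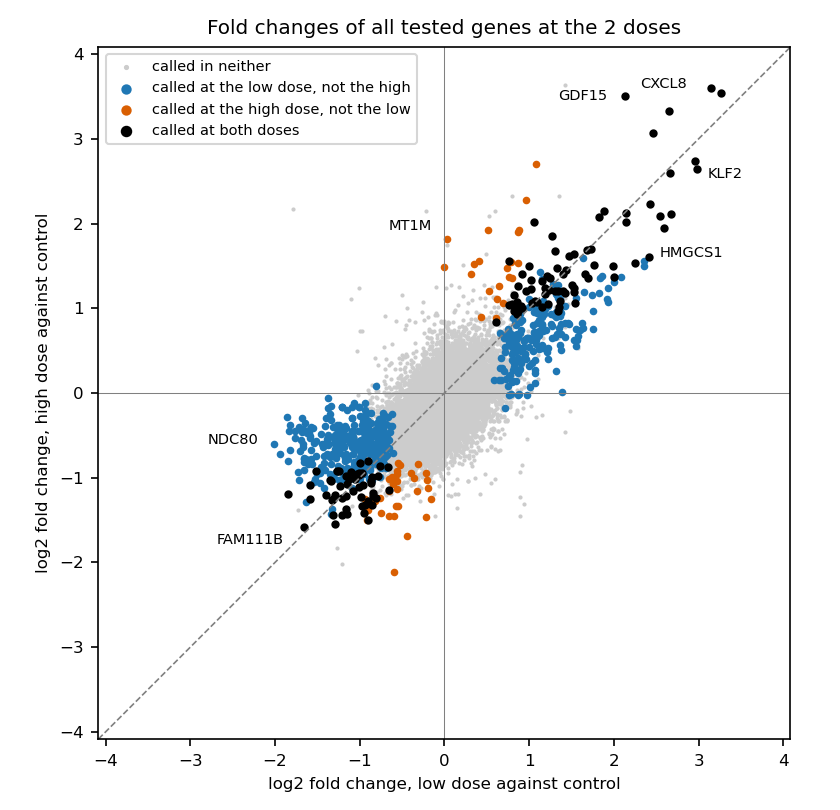
Log2 fold change against control at the low dose (horizontal axis) and the high dose (vertical axis) for each of the 22109 tested genes. Colours show where a gene was called and the dashed line marks equal change. Genes called at both doses, in black, lie in the upper right (73 genes) and lower left (53 genes), and GDF15 (2.13 and 3.51) and NDC80 (-2.01 at the low dose) are among the labelled genes.

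Set directly against the low dose, the high dose differed in 1 gene. The metallothionein gene MT1M was higher by 1.79 ± 0.18 (SE; log2 scale; 2 against 3 arrays; adjusted p = 0.0200), at 3.10 ± 0.20 (SD, n = 2) against 1.31 ± 0.18 (SD, n = 3) and 1.28 ± 0.14 (SD, n = 3) in controls. The 10th percentile of the tested genes lay at 1.18 to 1.28 on the 8 arrays, so MT1M was not shown to be above background in the low and control groups, and its difference is only a lower bound if it was not. Genes with the next smallest p, none of which passed, were TC2N (1.49 ± 0.22, adjusted p = 0.270), GDF15 (1.38 ± 0.22, adjusted p = 0.296), RASD1 (1.18 ± 0.20) and CLEC2B (1.15 ± 0.20) on the higher side. On the lower side were ALOX5AP (-1.32 ± 0.23), TCN1 (-1.32 ± 0.24), VSTM4 (-1.06 ± 0.19), CEP295NL (-1.05 ± 0.19) and ARHGAP22 (-0.94 ± 0.18) (adjusted p = 0.300 for those without a value). No gene was lower with limma, against 566 higher and 1349 lower at an unadjusted p under 0.05. Without control 3, which takes part through the shared spread, 74 genes were higher and 100 lower. The call of MT1M ended when any array other than control 3 was left out, with adjusted p-values up to 0.226 and differences between 1.65 and 1.93. With the replicate block, whose numbers did not pair the high arrays, 21 genes were higher and 198 lower.

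As a group, the mitotic genes stood higher at the high dose than at the low dose: all 28 had a positive difference, with a median of 0.98. Of these, 24 passed adjusted over the list alone although none did over all genes (adjusted p = 9.70e-37, and adjusted p = 0.321 with an estimated correlation). On single arrays the mean log2 level of this list was 5.57, 5.44 and 5.07 at the low dose and 6.44 and 6.17 at the high dose. Homologous recombination genes had a median difference of 0.40, or 0.21 to 0.59 when 1 array was left out (0 of 12 passed, also adjusted over the list alone; adjusted p = 1.39e-05, and adjusted p = 0.468 with an estimated correlation). Metallothioneins had 0.37, or 0.29 to 0.59 when 1 array was left out (1 of 9, and 4 adjusted over the list alone; adjusted p = 1.44e-05, and adjusted p = 0.158 with an estimated correlation). The lists of cholesterol (-0.27), fatty acid (-0.39), NRF2 (-0.29), xenobiotic (-0.34) and mesenchymal genes (-0.26) had lower medians at the high dose and the interferon list a higher one (0.17), with adjusted p-values between 0.00107 and 0.0352, all at 0.792 with an estimated correlation. Without high 2, 4 lists were called in place of 9, and those of the cholesterol, fatty acid, NRF2, interferon and xenobiotic lists ended, with medians of -0.10, -0.29, -0.18, 0.08 and -0.21. The interferon call was the least stable and ended under 15 of 24 alternative settings, among them the fits without low 3 (median 0.06, adjusted p = 0.0867), high 1 (0.0887) and control 3 (0.0508). That of the xenobiotic list ended under 7, also without low 3 (adjusted p = 0.0597), and that of the fatty acid list under 5. The DNA replication list did not differ by this test (median -0.04; adjusted p = 0.350).

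Of 1608 long non-coding RNA genes tested, 4 rose and 8 fell at the low dose, or 0.746% against 3.18% of the other genes (Fisher's exact test, two-sided, p = 1.69e-10). At the high dose 1 rose and 7 fell (0.498% against 0.839%; p = 0.192 by the same exact test). This test takes genes as independent, although they were measured on the same arrays. The genes were not matched on level, so a weaker response of long non-coding RNAs is not shown. NPPA-AS1 (1.38 ± 0.20), LINC-PINT (1.27 ± 0.22), a p53-regulated transcript, and TLR8-AS1 (1.25 ± 0.21) rose at the low dose, and PCNA-AS1 (-1.33 ± 0.21), LINC02984 (-1.29 ± 0.23) and TMPO-AS1 (-1.16 ± 0.14) fell. At the high dose TLR8-AS1 rose (1.36 ± 0.23) and LINC02984 (-1.54 ± 0.26), PCNA-AS1 (-1.27 ± 0.24) and LINC01116 (-1.24 ± 0.22) fell. These high-dose calls ended under 9, 7, 8 and 9 of 21 alternative settings. Antisense transcripts overlap the gene on the other strand, and whether each probe set reads 1 strand was not tested. With the replicate block 22 long non-coding RNA genes were called at the low dose. Counts moved with single arrays, to 3 at the low dose without low 2 and at the high dose from 8 to 35 without control 3, to 0 without control 1, control 2 or high 2, and to 1 without low 1, low 2 or high 1. Of 1450 small RNA genes, 1 rose and 5 fell at the low dose (19 called with the replicate block, and 16 without control 3), and 2 rose and 6 fell at the high dose (75 called without control 3, and 0 to 3 without any 1 of the other arrays except low 3).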

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

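The tests in this part were chosen before their own results were seen, after the patterns themselves had been seen; none was chosen after its result. A direct test between the treated groups singled out 1 gene and 9 gene lists, and probe sets outside the gene-level comparisons also moved. MT1M was higher at the high dose than at the low dose by 1.79 on the log2 scale. Median differences between the doses were 0.98 for mitotic genes, 0.40 for homologous recombination, 0.37 for metallothioneins and 0.17 for interferon-stimulated genes. They were -0.39 for fatty acid synthesis, -0.34 for xenobiotic metabolism, -0.29 for NRF2 targets, -0.27 for cholesterol genes and -0.26 for mesenchymal genes. None of these lists was called with an estimated correlation. Among the 27904 probe sets unnamed here, 16 were higher at the high dose and 50 at the low dose than in the controls when all 53617 rows were tested, beside 7 and 25 lower ones.

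The number of genes that differed between the low dose and control was set against other splits of the same 6 arrays. The real split called 664 genes. Of the 10 ways to part the 6 arrays into 3 and 3, only the real 1 gave as many, and the highest count among the others was 0. With 10 splits no share under 0.05 can be reached, so these are too few to judge chance. Among the 4 splits that part all 3 same-numbered pairs of arrays, the 3 other than the real one called 0 genes, and the 6 that keep 2 pairs together called 0 as well. Every split other than the real one mixes control and low arrays, which puts any difference between the groups into the spread. Counts of 0 are then likely, so they judge neither chance nor pairing.

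Mitotic genes were lower at the low dose (median -1.49) and higher at the high dose than at the low dose (median 0.98). Both differ from the drift of equally bright genes: among 10000 random lists matched on level, the lowest median was -0.37 for the low dose and the highest was 0.085 for the difference between doses. These lists hold unrelated genes, so they cannot judge a shift that mitotic genes share between samples. The untreated controls alone lay between 6.58 and 7.26 in the mitotic list. Camera with an estimated correlation gave adjusted p = 0.144 at the low dose and 0.321 between the doses, and fry gave 0.0107 and 0.253. No single treated array made the second difference, since the lowest median without 1 of the 5 treated arrays was 0.79. Control 3, where these genes were highest, adds to the first, but without it the median was still -1.31. A treatment effect on proliferation that differs between the groups may account for the pattern as a hypothesis; cell density and cell cycle phase were not measured, and the unsettled identity of the treatments leaves open whether dose or compound separates the groups.

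Control 3, low 3 and high 2 deviated from their groups in the same direction, with a mean correlation of 0.190 across genes. The mitotic list was an exception. Its mean log2 level was higher on control 3 (7.26 against 6.61 and 6.58 on the other controls). It was lower on low 3 (5.07 against 5.57 and 5.44) and on high 2 (6.17 against 6.44). All 3 arrays thus enlarged the mitotic fall against control. A treated sample under the label control 3 is argued against by its place: over the 296 genes called without it at both doses, control 3 lay at 0.254 of the way from the controls to the treated arrays. The other controls lay at 0.054 and 0.064 and treated arrays between 0.846 and 1.06, each over the genes called without that array (14 to 122), so these positions are not on the same genes. Unequal signal distributions remain open, since after quantile normalization the correlation was 0.0724, lower than before but not gone. A shared handling of these arrays may be another candidate explanation, which no label allowed to test.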

How the results depend on the processing

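Fits without control 3 and low 3, without control 3, low 3 and high 2, and with the replicate block over control and low arrays alone were chosen only after the result was seen. Of 3539 values of called genes and lists under alternative settings, 3075 kept the call and 464 lost it. The 9 named genes not called between the doses gave 187 more, of which 45 gained a call and 142 stayed without. In 0 of these 3726 values did a gene change sign or was a list called in the opposite direction. Changes in the direction of a list test that was not called were not counted. The median of a list did change sign 14 times, over 5 lists with medians near 0 in most cases: hypoxia at the high dose (-0.05, up to 0.23), p53 targets at the high dose (0.08, down to -0.06), autophagy at the high dose (0.10, down to -0.05), NRF2 at the high dose (0.07, down to -0.01) and mesenchymal genes at the low dose (0.21, down to -0.02). Of the named genes, 6 of 45 at the high dose and 44 of 66 at the low dose kept their call under every setting that tested them. MT1M, among those at the high dose, was not tested with genes above the median level only. The counts of genes were far less stable. Where no cause is given, the cause was not tested. Background signal was not used here, so how far dim genes limit the counts is unknown.

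Testing all 53617 probe sets, which raises the number of tests, called 57 higher and 16 lower probe sets at the high dose (57 and 16 at least 2-fold), and 206 lower ones at the low dose. Unnamed ones are among them, 16 and 7 at the high dose and 25 of those lower at the low dose, and only 34 higher and 9 lower genes were shared with the genes called at the high dose. There were 0 and 4 long non-coding and 1 and 0 small RNA genes at the high and low dose, and 0 between the doses, also at 2-fold. With genes above the median level only, which lowers it, 144 were lower at the high dose, 10 small RNA genes were called at the low dose, and 0 genes were higher between the doses, 2-fold or not, since MT1M is below that level. Quantile normalization gave 326 higher and 133 lower at the high dose (177 and 40 at 2-fold), and 612 higher at the low dose. It called 16 and 24 long non-coding and 21 small RNA genes (low dose), and 2 genes higher between the doses (2 at 2-fold). Subtracting array medians gave 57 lower at the high dose, 41 at 2-fold. At an adjusted p under 0.01, a stricter threshold, there were 34 higher and 7 lower at the high dose (all at 2-fold: 34 and 7), and 108 and 135 at the low dose (102 and 125 at 2-fold). There were then 0 and 4 long non-coding, 1 and 0 small RNA genes, and 0 between the doses, 2-fold or not.

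Array weights gave 235 higher and 769 lower at the high dose (142 and 263 at 2-fold), and 961 and 1094 at the low dose. They gave 35 and 61 long non-coding and 43 and 60 small RNA genes, and 17 higher and 52 lower between the doses (16 and 48 at 2-fold). Fitting the arrays of 2 groups only, which leaves fewer samples to estimate the spread, gave 37 higher and 9 lower at the high dose (37 and 9 at 2-fold), with 0 long non-coding and 3 small RNA genes there. It gave 29 higher and 24 lower between the doses (29 and 24 at 2-fold). With the replicate block, whose numbers did not pair the high arrays, there were 197 higher and 1031 lower at the high dose (300 lower at 2-fold) and 483 higher at the low dose. The block gave 37 and 22 long non-coding and 37 and 19 small RNA genes, 21 higher and 198 lower between the doses (16 and 139 at 2-fold), and a correlation between the doses of 0.516. The block ended 2 list calls, hypoxia at the high dose and interferon between the doses, and no call of a named gene. It added calls of 7 of the 9 named genes that had not passed between the doses, and changed no other call of a named gene or of a list called without it. Over control and low arrays alone the block ended 4 calls of named genes and no list call.

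Leaving out 1 array at a time, with a lone high array assumed to vary like the other groups, gave these ranges. At the high dose 13 to 250 genes were higher and 1 to 740 lower (13 to 167 and 1 to 347 at 2-fold), with 0 to 35 long non-coding and 0 to 75 small RNA genes. At the low dose 96 to 252 were higher and 170 to 408 lower (93 to 189 and 127 to 213 at 2-fold), with 3 to 14 long non-coding and 2 to 16 small RNA genes. Between the doses 0 to 74 were higher and 0 to 100 lower (0 to 60 and 0 to 62 at 2-fold), with 4 to 11 lists called. The correlation between the doses ranged from 0.522 to 0.670, and the highest counts at the high dose and between the doses came without control 3. The median moved by 1.5 times or more without some array in 9 of the 16 lists called at the high dose, 13 of 21 at the low dose and 6 of 9 between the doses. Leaving out control 3, low 3 and high 2 gave 562 higher and 1001 lower at the high dose (261 and 253 at 2-fold), and 676 and 602 at the low dose. It gave 55 and 31 long non-coding and 134 and 44 small RNA genes, and 93 higher and 127 lower between the doses (82 and 91 at 2-fold). Leaving out control 3 and low 3 gave 432 and 1953 at the high dose (177 and 371 at 2-fold), and 398 higher at the low dose. It gave 71 and 19 long non-coding and 123 and 24 small RNA genes, and 141 higher and 759 lower between the doses (61 and 174 at 2-fold).

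With an estimated correlation between genes, camera called 1 list at the high dose, 0 at the low dose and 0 between the doses, in place of 16, 21 and 9. Fry called 5, 9 and 0, and camera on ranks 17, 21 and 9. At the high dose fry called the NF-κB, replication, homologous recombination, metallothionein and histone lists, the last not called by camera. At the low dose these 5 were joined by the mitotic, cholesterol, NRF2 and glucocorticoid receptor lists. Adjusted p-values of these lists by fry lay between 0.00539 and 0.0394. Fry does not compare a list with other genes, and 33 of 46 list calls ended under it. Of the other settings, the row kept per gene, an intensity trend and a robust trend kept every count of genes within 1.5 times of the main one.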

Other observations

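The 2 tests of the order of the doses in this part were chosen only after the result was seen. Several programmes that a plant extract at sublethal concentrations could have touched were not called at either dose. Endoplasmic reticulum chaperones, the folding machinery induced by unfolded proteins, had medians of -0.13 at the high dose and -0.04 at the low dose (camera adjusted p = 0.520 and 0.0803, 19 genes; 0 passed at either dose). Cytosolic heat shock proteins had -0.10 and -0.00 (0.301 and 0.613, 9 genes), of which 1 was lower at the low dose. Mitochondrially encoded genes had -0.04 and 0.03 (0.743 and 0.649, 8 genes), and LXR targets of cholesterol efflux -0.12 and -0.10 (0.620 and 0.985, 8 genes). In a list of 18 well-studied long non-coding RNAs and snoRNA hosts (0.301 and 0.447), SNHG1 fell at the low dose (-0.95 ± 0.19, picked out after its value was seen), at -0.96 ± 0.22 at the high dose without passing. Fatty acid synthesis and apoptosis regulators were not called at the high dose (0.615 and 0.179), nor were xenobiotic metabolism, histones and mesenchymal genes (0.183, 0.153 and 0.658), although MMP1 rose there by 1.21 ± 0.17. The histone list still had a median of -0.47 at the high dose, near the -0.55 of the low dose. There 3 of its 8 genes fell adjusted over the list alone, and fry gave an adjusted p of 0.0252. A histone fall particular to the low dose is therefore not shown.

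None of the lists of markers of cells that the cultures should not hold was called. Luminal breast epithelial markers had adjusted p-values of 0.476 at the high dose and 0.759 at the low dose (14 genes), leukocyte markers 0.0757 and 0.0529 (12 genes, of which 11 were higher at the low dose, with a median of 0.13) and fibroblast markers 0.658 and 0.207 (9 genes). The fibroblast collagen gene COL1A1 rose at the low dose (0.76 ± 0.16; picked out after its value was seen) and stood at -0.03 ± 0.18 at the high dose.

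The high dose did not change genes more than the low dose across all arrays. Of 702 genes called for the mean of both treated groups, 36.6% changed more at the high dose, with median sizes of 0.82 at the high dose and 0.98 at the low dose. The median change over all genes was -0.12 at the high dose and -0.04 at the low dose, a drift that enters these sizes. A response that keeps growing between 2 doses of 1 extract would tend to put this share over 50%, but one that levels off need not. Without control 3 it was 61.1% of 1115 genes, and without any other single array between 28.8% and 45.5%, so which dose changed genes more depended on control 3. The source names raise the hypothesis that the groups received different treatments, which could move genes in opposite directions. Of the genes called in both comparisons 0 did so, but the shared controls make opposite calls rarer. Different treatments may also move genes alike, so neither reading of the labels is excluded.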
